A study of Homo sapiens with 30 samples.

How the data were processed

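Poly(A) RNA from 2 human myeloma cell lines, MM.1S and RPMI-8226, was measured by single-read RNA sequencing in 30 libraries. Each line carried a constitutive short hairpin RNA (shRNA) from a lentivirus and was selected with puromycin. Of the 5 groups per line, 1 carried a non-targeting hairpin (shNTC), 2 carried hairpins against NOTCH1 (shN1_1 and shN1_2) and 2 carried hairpins against NOTCH2 (shN2_1 and shN2_2), with 3 replicates each. The labels do not say whether the replicates came from separate transductions or separate cultures, so every p measures the spread between these samples only. The kit was non-directional, so reads of overlapping or antisense genes, and of small RNA genes within their hosts, could not be told apart. Genes with close copies, such as CCL3L3, CCL4L2, the HLA genes and the immunoglobulin genes, had less certain values for the same kind of reason.

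The submitters' processing notes name CASAVA, STAR 2.7.2b, featureCounts 1.6.4 and DESeq2 with genome build GRCh38.p13, without saying what each did or in which order. Per the deposited tables, values were transcripts per 1e+06 (TPM) for 46660 genes in 15 libraries of each line, and every library summed to 1e+06. The authors also deposited variance-stabilised values per library on a log2 scale. The authors' 8 tables of each hairpin against shNTC held a moderated log2 fold change from DESeq2, with the standard error of that log2 fold change as a further measure by the authors. In those tables the p-value and the adjusted p-value came from the authors' Wald test. The deposited mean normalised signal of each gene in those tables was above 0 for 633 genes in MM.1S and 1635 genes in RPMI-8226 that had no read in the 15 libraries of the line, so the libraries behind those tables were not fully known, and the tables served only as an alternative.

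Multiplying TPM by exon length gave whole numbers of reads in every library (100% of values above 0 within 0.02 of a whole number), which gave the depth. It ran from 6532988 to 37382560 reads in MM.1S, with a median of 26796317, and from 13932130 to 29718804 in RPMI-8226, with a median of 24462416. The lowest depth belonged to shN2_2 replicate 2 of MM.1S.

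The main test was limma 3.58.1 in R 4.3.3, with a mean trend of the variance, on log2 of TPM plus 0.5. Genes entered with a TPM of at least 1 in at least 3 of the 15 libraries of the line, which left 16395 genes in MM.1S and 16706 in RPMI-8226. All 15 libraries of a line shared 1 fit, and each hairpin was compared with shNTC. A gene passed with a Benjamini-Hochberg adjusted p under 0.05, computed for each comparison over all its genes. Genes past in both hairpins of a receptor with the same sign were counted, since such a change does not rest on 1 hairpin. The mean of the Notch1 hairpins was compared with the mean of the Notch2 hairpins in the same fit. The change in MM.1S was compared with that in RPMI-8226 over the 14709 genes tested in both lines. Standard errors come from that fit and standard deviations (SD) from the 3 libraries of a group. For both hairpins of a receptor the same controls were used, so genes shared by both were set beside the product of the counts divided by the genes tested and beside 20 simulations with shared controls and no change.

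A total of 32 gene lists, fixed before the data were examined and written from general knowledge, held 1308 entries, of which 1305 matched a listed gene. Of these, 853 were tested in MM.1S and 909 in RPMI-8226. Lists with at least 5 tested members were tested with camera (preset correlation of 0.01) on the mean of both hairpins of a receptor. Each list also has a count adjusted over the list alone. The lists cover Notch receptors and ligands, Notch signalling machinery, canonical Notch target genes, 5 groups of matrix genes, integrins and adhesion receptors, plasma cell identity, B cell identity and myeloma oncogenes. They also cover the unfolded protein response, the ATF4 amino acid response, the type I interferon response, MHC class I, NF-kB targets, p53 targets, DNA replication and E2F targets and mitosis. The last ones are ribosome biogenesis, cytoplasmic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol and fatty acid synthesis, the BCL2 family, the proteasome and markers of T and NK, myeloid, stromal and endothelial, epithelial and erythroid cells.

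Genes were named by a fixed rule. It takes the 4 NOTCH genes and the canonical Notch targets. For each line and receptor it takes the 6 highest and 6 lowest mean changes among genes past in both hairpins with a mean TPM of at least 5, and up to 4 members per list past in both hairpins. It also takes up to 10 genes past in all 4 comparisons of a receptor or of a line or in all 8, 5 in each direction between receptors or lines, and 2 in each direction per hairpin. A few genes named for other reasons are marked as chosen after the values were seen. A list of immediate-early genes was also written after the values were seen.

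The pipeline was tested on simulated data with the depths of each line and, for all genes, the median spread of its well-covered genes. Genes with a larger spread and single libraries apart from their group were absent. Recovery in the real data may therefore be lower and false calls more frequent. Of the genes changed 1.5-fold in both hairpins, 91.2% were recovered in MM.1S and 77.9% in RPMI-8226, and of those changed 2-fold, 95.5% and 93.9% were recovered. In each line 1 unchanged gene passed in both Notch1 hairpins. Alternatives were the deposited variance-stabilised values, a pseudocount of 0.1, no filter, a minimum TPM of 5, median-ratio scaling, replicate number as a block, only the compared groups in the fit, each library left out in turn and the authors' deposited adjusted p. For lists they were an estimated correlation and the fry test. Added after the values were seen were voom and a fit without 3 libraries of MM.1S high for immediate-early genes. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.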

Results

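The data are TPM values of 46660 genes in 30 poly(A) RNA libraries of MM.1S and RPMI-8226, lines grown from multiple myeloma, a cancer of plasma cells. Each line has 5 groups of 3 libraries: non-targeting shNTC, shN1_1 and shN1_2 against NOTCH1, and shN2_1 and shN2_2 against NOTCH2. Libraries held 6532988 to 37382560 reads in MM.1S and 13932130 to 29718804 in RPMI-8226. In MM.1S, immunoglobulin lambda genes took 17.6% to 18.0% of the TPM of the shNTC libraries and 14.2% to 16% of the Notch2 libraries. Levels are mean TPM ± SD with n = 3 libraries, and changes are log2 against shNTC of the same line with the standard error (SE) of the fit.

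The first comparison asked how far each hairpin lowered its own receptor. NOTCH1 and NOTCH2 encode cell surface receptors that are cleaved after ligand binding and then act with RBPJ on transcription. NOTCH1 (chromosome 9, 136494433 to 136546048, GRCh38.p13) fell in MM.1S from 20 ± 3.58 to 4.97 ± 0.212 TPM with shN1_1, which was 24.8% of the control (log2 -1.89, SE 0.10, adjusted p = 1.4e-06). With shN1_2 it fell to 6.46 ± 0.630 TPM, or 32.3% (log2 -1.55, adjusted p = 4.5e-06). NOTCH2 (chromosome 1, 119911553 to 120069703) fell in MM.1S from 17.6 ± 3.55 TPM to 35.0% with shN2_1 (log2 -1.42, SE 0.13, adjusted p = 3.5e-05) and to 42.8% with shN2_2 (log2 -1.16, adjusted p = 9.4e-05). In RPMI-8226, NOTCH1 fell from 20 ± 0.672 TPM to 27.0% with shN1_1 (log2 -1.80, SE 0.06, adjusted p = 6.8e-09) and to 49.2% with shN1_2 (log2 -0.99, adjusted p = 3.5e-08). NOTCH2 fell there from 49.8 ± 1.82 TPM to 23.7% with shN2_1 (log2 -2.03, SE 0.04, adjusted p = 1.3e-13) and to 27.0% with shN2_2 (log2 -1.85, adjusted p = 3.3e-12).

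The other receptor changed little. In MM.1S, NOTCH2 was at 79.4% of the control with either Notch1 hairpin (adjusted p = 0.17 and 0.12), and median-ratio scaling brought shN1_2 past the threshold (adjusted p = 0.041). NOTCH1 in the MM.1S Notch2 groups was at 103% and 90.3% (adjusted p = 0.73 and 0.38). In RPMI-8226, NOTCH2 with shN1_2 was at 90.9% (log2 -0.14, adjusted p = 0.0088) and with shN1_1 at 103% (adjusted p = 0.49). NOTCH1 in RPMI-8226 was at 107% and 111% with the Notch2 hairpins (adjusted p = 0.20 and 0.077), and both were past the threshold after median-ratio scaling (adjusted p = 0.016 and 0.041). The authors' deposited adjusted p passed for NOTCH2 in both MM.1S Notch1 groups (0.0205 and 0.0021), for NOTCH1 in MM.1S shN2_2 (0.0297) and in both RPMI-8226 Notch2 groups (0.0106 and 0.0301), and did not for NOTCH2 in RPMI-8226 shN1_2 (0.106). NOTCH3 was below the filter in both lines, and NOTCH4 passed the filter in MM.1S only and was not called there.

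**Figure D1:**
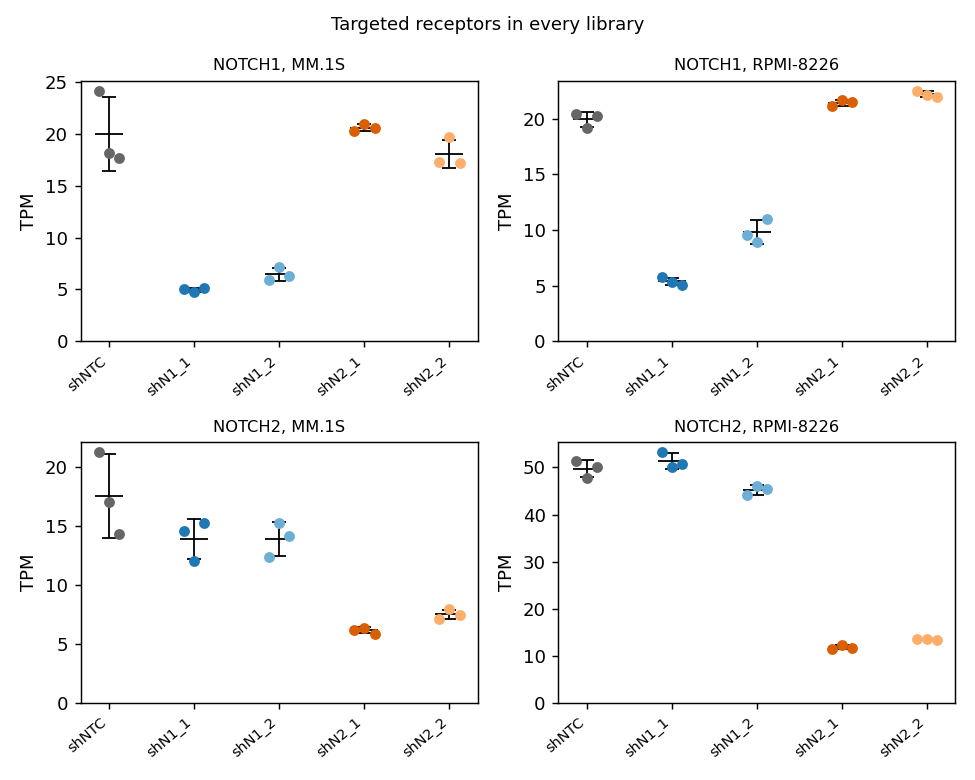
TPM of NOTCH1 and NOTCH2 (vertical axes, from 0) in the 5 groups of each line, with a dot per library, a dash for the mean and whiskers for the SD of 3 libraries. Each receptor was lowest in its own 2 hairpin groups, between 23.7% and 49.2% of shNTC.

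Canonical Notch target genes did not pass as a list with either receptor in either line. In MM.1S Notch1 they were past the threshold as a lower list without shN1_2 replicate 1 (adjusted p = 0.048) and without the 3 libraries high for immediate-early genes (adjusted p = 0.029). In MM.1S Notch1 none of 17 tested members passed in both hairpins, in MM.1S Notch2 1 rose and 1 fell, in RPMI-8226 Notch1 3 of 19 fell, and in RPMI-8226 Notch2 2 rose and 4 fell (camera adjusted p = 0.11, 0.11, 0.93 and 0.58). Adjusted over the list alone, the counts of higher and lower genes were 0 and 0, 1 and 1, 0 and 4, and 2 and 4. HES4, a transcriptional repressor of the HES family, fell in RPMI-8226 from 23.5 ± 0.928 TPM to 7.49 with shN2_1 (log2 -1.59, adjusted p = 3e-08) and 13.6 with shN2_2 (log2 -0.78, adjusted p = 5.5e-05). With shN1_1 HES4 was at 19.2 TPM (adjusted p = 0.082), a call that passed with the variance-stabilised values and with voom, and with shN1_2 it fell to 10.5 TPM (log2 -1.13). HES1, the best known target, rose in RPMI-8226 with 1 hairpin of each receptor, from 1.80 TPM to 5.61 with shN1_2 and 6.99 with shN2_2 (log2 1.40 and 1.69). It was at 1.94 and 2.12 TPM with the other hairpins (adjusted p = 0.85 and 0.56). In MM.1S, HES1 was 10.7 ± 1.6 TPM in shNTC and 17.2 ± 8.47, 15.2 ± 7.87, 18.1 ± 7.69 and 11.7 TPM in the hairpin groups, and none passed. BCL3, an NF-kB cofactor, fell in both RPMI-8226 Notch1 hairpins (log2 -0.65 and -0.63) and with shN2_1 (log2 -1.24), and rose with shN2_2 (log2 0.38). SAT1, of polyamine breakdown, and the cyclin gene CCND1 were the other targets lower in both RPMI-8226 Notch1 hairpins (log2 -0.27 and -0.47, and -0.39 and -0.19). The SAT1 call ended without shNTC replicate 1 or 3 or shN1_1 replicate 3 (adjusted p up to 0.072) and the CCND1 call without shNTC replicate 3 or shN1_2 replicate 2 (adjusted p up to 0.068). In the RPMI-8226 Notch2 groups CD300A, HES7 and MYC were also lower in both hairpins, MYC by a log2 change of -0.10 and -0.21 from 462 TPM, a call that ended after median-ratio scaling and without shNTC replicate 1 or 3 or shN2_1 replicate 1 (adjusted p up to 0.073). TRIB2 and HES6 were higher in both (log2 0.48 and 0.26, and 0.52 and 0.40). The TRIB2 call ended without shNTC replicate 3 or shN2_2 replicate 1 or 2 (adjusted p up to 0.098), and the HES6 call without shNTC replicate 1 or 2 or shN2_2 replicate 1 or 3 (adjusted p up to 0.10). In MM.1S Notch2, CD300A fell from 26.9 to 20.3 and 14 TPM (log2 -0.39 and -0.92), and SHQ1 was the single target past the threshold as higher, which it was not after median-ratio scaling or without any single shNTC library, shN2_1 replicate 1 or shN2_2 replicate 1 or 2 (adjusted p up to 0.10). MYC in MM.1S was past the threshold only with shN2_1 (log2 0.26, adjusted p = 0.0075). HEY1, HEY2, HES2, NRARP and DTX1 were not called in both hairpins of any receptor or lay below the filter.

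The genes called in each hairpin group ranged from 833 in MM.1S shN1_1 to 8157 in RPMI-8226 shN2_1, out of 16395 and 16706 tested. In MM.1S, shN1_1 had 455 higher and 378 lower genes, shN1_2 had 1648 and 399, shN2_1 had 3211 and 390, and shN2_2 had 3131 and 781. In RPMI-8226 the counts were 765 higher and 1274 lower with shN1_1, 2952 and 4634 with shN1_2, 2552 and 5605 with shN2_1, and 2833 and 3131 with shN2_2. The excess of higher genes in MM.1S depended on the scaling. After median-ratio scaling the MM.1S counts were 457 and 570, 771 and 962, 936 and 1238, and 1098 and 1552, and those of RPMI-8226 were 969 and 1123, 3831 and 3827, 3858 and 4049, and 3024 and 3112. The median change of all tested genes in MM.1S was 0.00, 0.07, 0.12 and 0.10 log2 for the 4 hairpins, so small changes there are best read against that shift. Single libraries moved some MM.1S counts by over 1.5 times. The shN1_1 count of 833 was 324 and 513 without shNTC replicate 1 and 2, and 332, 250 and 395 without shN1_1 replicate 1, 2 and 3. The shN1_2 count of 2047 was 1322 without shNTC replicate 1, and 1122 and 694 without shN1_2 replicate 2 and 3. The shN2_1 count of 3601 was 2119, 2255 and 1992 without shN2_1 replicate 1, 2 and 3.

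**Figure D2:**
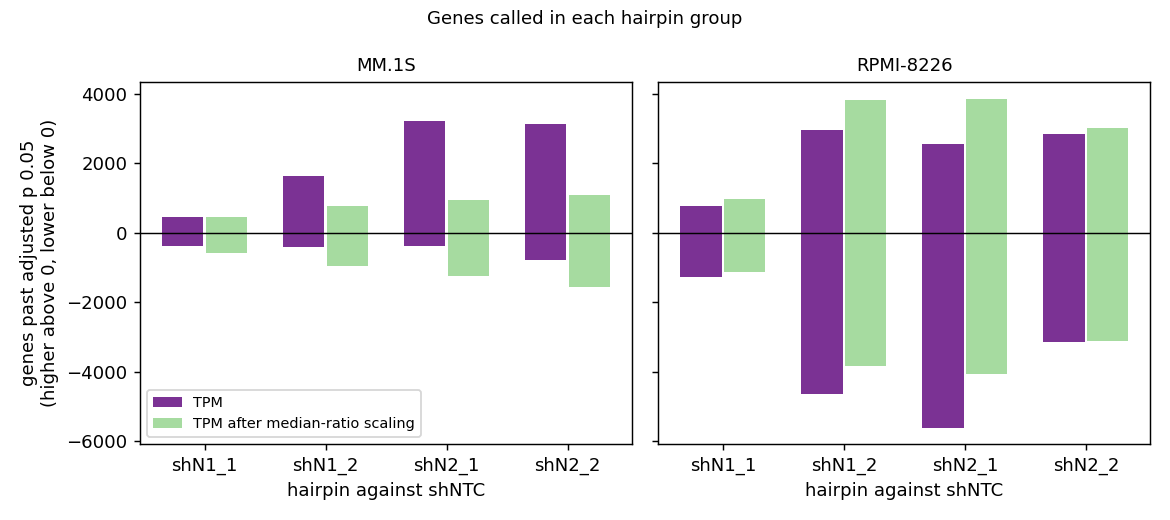
Number of genes with adjusted p under 0.05 against shNTC in each hairpin group of both lines, with higher genes above 0 and lower genes below 0, from TPM and after median-ratio scaling. In MM.1S shN2_1 the bars are 3211 and 390 from TPM and 936 and 1238 after scaling.

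Lowering NOTCH1 in MM.1S went with 405 genes called in both hairpins, and besides NOTCH1 itself CD52, CD68, CDH2 and IL6R were lower. CD68 and CDH2 were also lower in both Notch2 hairpins. Here and below, loss of a receptor was not told apart from other effects of hairpins or culture. CD52, a small glycoprotein on lymphocytes, fell from 31.6 ± 2.04 to 18.8 ± 2.21 TPM with shN1_1 and to 20 ± 1.82 with shN1_2 (log2 -0.74 and -0.64, SE 0.11, adjusted p = 0.0039 and 0.0038). CD68, a lysosomal protein used as a macrophage marker, fell from 45.4 ± 2.12 to 31.4 and 33.0 TPM (log2 -0.53 and -0.45, SE 0.06). CDH2, which encodes N-cadherin, fell from 23.8 ± 2.04 to 17.6 and 17.2 TPM (log2 -0.42 and -0.45, SE 0.06). IL6R, the receptor for the myeloma growth factor interleukin-6, fell from 159 ± 12.2 to 125 and 128 TPM (log2 -0.35 and -0.31, SE 0.06). The 6 genes with the largest rises were the small RNA genes SNORD45A, MIR7-1, SNORD83A, SNORA80B, SNORD99 and SNORA4. SNORA4 rose from 24.4 to 43.5 and 52.3 TPM. SNORD45A, at 11 ± 6.6 TPM in shNTC and 29.6 and 27.4 with the hairpins, was past the threshold but not without shNTC replicate 2 or shN1_1 replicate 2 or 3 (adjusted p = 0.050 to 0.066). The calls of MIR7-1, SNORD83A and SNORD99 ended without any single library of the compared groups, except shN1_1 replicate 2 for MIR7-1 and shNTC and shN1_2 replicate 2 for SNORD99 (adjusted p up to 0.15, 0.14 and 0.14). That of SNORA80B ended without shNTC replicate 1 or 2, shN1_1 replicate 2 or 3 or shN1_2 replicate 3 (adjusted p up to 0.090). Among the largest falls, AHNAK, a large scaffold protein, was at 31.3 ± 32.0 TPM in shNTC and 5.22 and 3.98 TPM with the hairpins (log2 -1.99 and -2.34). Its shNTC mean rested on replicate 1, and the call ended without that library, without shNTC replicate 2 or without any single library of the Notch1 groups (adjusted p = 0.054 to 0.12, with a mean change of -1.37 without shNTC replicate 1).

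Of cytoplasmic ribosomal proteins with Notch1 in MM.1S, 22 of 60 rose in both hairpins and none fell, or 29 adjusted over the list alone (median log2 0.15, camera adjusted p = 8.0e-14, adjusted p = 0.68 with an estimated correlation). RPS29 rose from 32.0 to 42.3 and 44.0 TPM, RPS20 from 823 to 1071 and 1054, RPS21 from 508 to 648 and 646, and RPL34 from 410 to 514 and 511. After median-ratio scaling 7 of the 60 rose. Of 46 oxidative phosphorylation genes, 6 rose, or 13 adjusted over the list alone, among them COX6C and ATP5PO (log2 0.27 and 0.28, and 0.24 and 0.28; camera adjusted p = 4.6e-06, adjusted p = 0.68 with an estimated correlation). After scaling 1 of the 46 rose, and the calls of COX6C and ATP5PO also ended without shN1_1 replicate 1 or 2, and that of COX6C without shNTC replicate 1 (adjusted p up to 0.057). Of 27 integrins and adhesion receptors 5 fell, or 6 adjusted over the list alone (camera adjusted p = 0.00038, adjusted p = 0.68 with an estimated correlation). They included CDH2, the endothelial and leukocyte protein PECAM1 (5.08 to 3.84 and 2.79 TPM) and the integrin ITGB7 (8968 to 8053 and 7772 TPM). The calls of PECAM1 and ITGB7 ended without shNTC replicate 1 or 2 or shN1_1 replicate 2, and also without shN1_1 replicate 1 for PECAM1 and replicate 3 for ITGB7 (adjusted p up to 0.086 and 0.074). The remaining lists past the threshold had at most 2 members called in a direction. They were, as lower lists, cholesterol and fatty acid synthesis (1 of 33 rose and 1 fell, camera adjusted p = 1.1e-05), p53 targets (0 of 27, 0.0045), interferon response (0 of 36, 0.012), Notch signalling machinery (0 of 25, 0.013), ribosome biogenesis (1 of 51 rose, 0.013), DNA replication and E2F targets (1 of 50 rose, 0.045) and myeloma oncogenes (1 of 30 rose and 2 fell, 0.045; median -0.01 and mean 0.07). Mitosis was a higher list (1 of 46 rose, 0.031). The hairpins moved the E2F targets apart, with 1 higher and 12 lower with shN1_1 (median -0.11) and 9 higher and 0 lower with shN1_2 (median 0.10). Interferon genes had medians of -0.17 and 0.02, and of the cholesterol genes 1 was lower with shN1_1 and 13 with shN1_2. After median-ratio scaling myeloma oncogenes and mitosis did not pass (adjusted p = 0.051 for both). With an estimated correlation none of the 11 lists held (adjusted p = 0.57 to 0.71 for these 8). Without shNTC replicate 1, 7 lists passed. Notch machinery, ribosome biogenesis, E2F targets, myeloma oncogenes and mitosis then did not (adjusted p = 0.14, 0.27, 0.22, 0.14 and 0.75), and ATF4 genes did (adjusted p = 0.013). Ribosome biogenesis was also lost without shNTC replicate 3 (adjusted p = 0.072), and mitosis without shN1_1 or shN1_2 replicate 3 (0.074 and 0.078). E2F targets were lost without shNTC replicate 3, shN1_1 replicate 2 or shN1_2 replicate 2 (0.67, 0.078 and 0.14), and myeloma oncogenes without shNTC replicate 2, shN1_1 replicate 1 or 3 or shN1_2 replicate 2 or 3 (0.066 to 0.13). Glycolysis and hypoxia passed without shNTC replicate 2 (adjusted p = 0.016). The lists that did not pass held few calls: 1 of 5 collagens, 2 of 28 plasma cell, 1 of 31 ATF4, 1 of 21 MHC class I, 1 of 54 matrix regulator, 2 of 37 matrix-affiliated and 2 of 58 secreted matrisome genes were higher in both hairpins. Of the last 3 lists, of 17 B cell genes and of 34 proteasome genes, 1 each was lower. None of 25 matrix glycoproteins, 33 unfolded protein response, 26 NF-kB, 35 glycolysis and hypoxia, 15 BCL2 family and 6 T and NK cell genes passed in both. Adjusted over the list alone, 2 matrix glycoproteins were higher, and 5 glycolysis and hypoxia genes higher and 2 lower. Lists with under 5 tested genes held 1 lower gene each among Notch receptors, myeloid, stromal and epithelial markers (NOTCH1, CD68, PECAM1 and SFN) and none among erythroid markers. The SFN call ended without shNTC replicate 1 or 2 or shN1_1 replicate 2 or 3 (adjusted p up to 0.11).

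In all, 315 genes were higher and 90 lower in both Notch1 hairpins of MM.1S, and 12 were called in opposite directions. Independent calls would share 45.7 and 9.20, although a control group of 3 libraries cannot be split to remove its share. In 20 simulations with shared controls and no change 0 were shared. The simulations drew each gene on its own, without shifts of whole libraries. Almost no gene could be called in them, so that 0 gives no support to the shared counts. After median-ratio scaling the counts were 220 and 233. The total of 405 was 175 and 251 without shNTC replicate 1 and 2, 181, 171 and 193 without shN1_1 replicate 1, 2 and 3, and 235 and 206 without shN1_2 replicate 2 and 3. With only the compared groups in the fit it was 26, and of CD52, CD68, CDH2 and IL6R only CD52 was then called in both hairpins.

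Libraries of MM.1S also differed within groups for immediate-early genes, which respond within minutes to stimulation. The median change of a list of these genes, written after the values were seen, was 1.39 in shN1_1 replicate 2, 0.98 in shN1_2 replicate 1 and 0.66 in shN2_1 replicate 2, and -0.33 to 0.09 in the other libraries. FOS was at 39.9 ± 18.8 TPM in shNTC, 135 ± 141 and 102 ± 99.2 in the Notch1 groups, and 50.5 ± 54.3 and 14.1 ± 6.16 in the Notch2 groups, and no hairpin passed. DUSP1, a phosphatase induced with them, was at 47.9 ± 23, 144 ± 131, 110 ± 94.9, 66.8 ± 59.8 and 30.1 TPM in the same order. Without these 3 libraries the genes called in both Notch1 hairpins numbered 94, and those in both Notch2 hairpins 913, and IL6R, SNORA4 and RPS29 were not among the first.

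**Figure D3:**
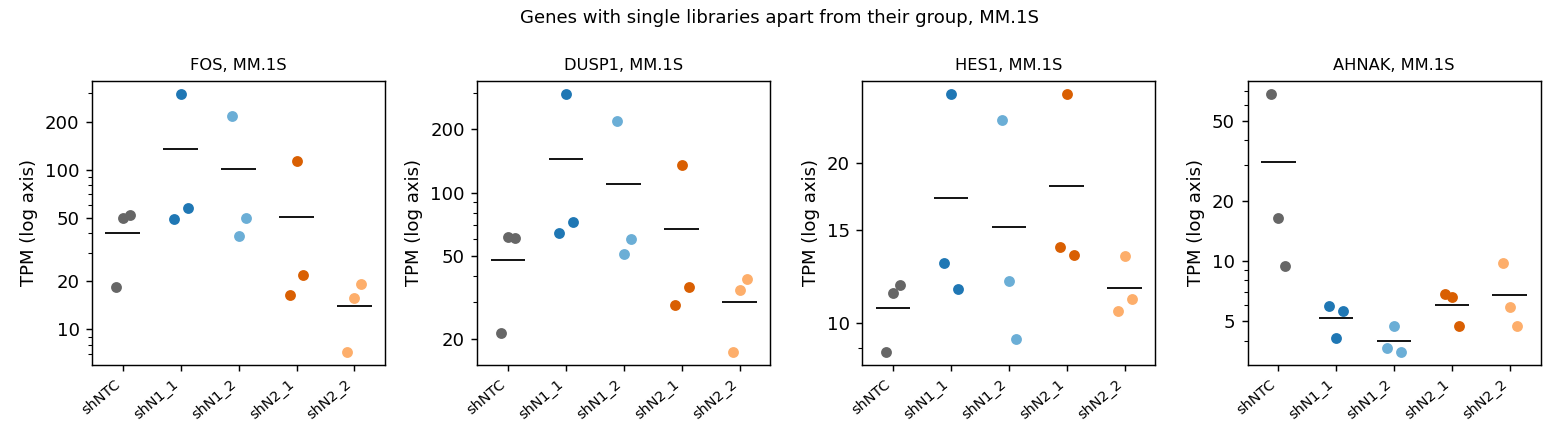
TPM of FOS, DUSP1, HES1 and AHNAK in the 15 MM.1S libraries (log axis), with a dot per library, by group. FOS had an SD of 141 TPM among the 3 shN1_1 libraries, and AHNAK an SD of 32.0 TPM among the 3 shNTC libraries.

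Lowering NOTCH2 in MM.1S went with lower lists of lipid synthesis, B cell and plasma cell genes. EMP3, a membrane protein, fell from 197 ± 17.5 to 89.2 ± 5.48 TPM with shN2_1 and to 74.8 ± 5.38 with shN2_2 (log2 -1.14 and -1.39, SE 0.08, adjusted p = 1.6e-05 and 6.5e-07). LGALS1, the lectin galectin-1, fell from 2640 ± 182 to 1894 and 1356 TPM (log2 -0.48 and -0.97, SE 0.07), and the calcium-binding protein gene S100A6 from 31.3 to 21.1 and 13.8 TPM (log2 -0.55 and -1.14, SE 0.12). SDC2, a heparan sulfate proteoglycan, rose from 5.29 ± 0.456 to 11.1 ± 0.111 and 8.99 ± 0.317 TPM (log2 1.00 and 0.71, SE 0.07). NDNF, a secreted factor, rose from 10.8 to 18.9 and 20.6 TPM, the transcription factor gene BHLHE22 from 3.16 to 5.96 and 6.92 TPM, and CENPV from 3.75 to 6.51 and 7.70 TPM. The largest falls by the rule were MIR30A (4716 ± 4570 to 757 and 494 TPM, over an exon length of 71 bases), AHNAK, CCL3L3 and VIM-AS1, which overlaps VIM. The MIR30A call ended without shNTC replicate 1 or shN2_1 replicate 1 or 3 (adjusted p up to 0.091), that of CCL3L3 without shNTC replicate 2 or 3 or shN2_1 replicate 1 or 3 (adjusted p up to 0.12), and that of AHNAK without any single library of shN2_1 or replicate 2 or 3 of shN2_2 (adjusted p up to 0.087).

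Of 33 cholesterol and fatty acid synthesis genes, 13 fell and 2 rose in both Notch2 hairpins of MM.1S, or 14 and 2 adjusted over the list alone (median log2 -0.16 against 0.11 for all genes, camera adjusted p = 3.6e-17, adjusted p = 0.021 with an estimated correlation). INSIG1, a sensor of sterols, fell from 439 ± 66.0 to 282 and 312 TPM (log2 -0.63 and -0.48). The fatty acid desaturase gene SCD fell from 357 to 234 and 277 TPM. Of 17 B cell identity genes 7 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.0e-08, adjusted p = 0.021 with an estimated correlation). The MHC class II genes HLA-DRB1 and HLA-DMA fell, HLA-DRB1 from 95.2 to 73.9 and 61.4 TPM, and the transcription factor gene ETS1 rose from 22.0 to 34.4 and 38.3 TPM. Of 28 plasma cell genes 3 fell and 1 rose, or 4 and 1 adjusted over the list alone and 8 and 0 after median-ratio scaling (camera adjusted p = 8.0e-06, adjusted p = 0.028 with an estimated correlation). Among them SLAMF7, the target of an approved antibody, fell from 410 to 347 and 315 TPM, and TXNDC5 from 2650 to 2256 and 2310 TPM. SLAMF7 was not called without the 3 libraries high for immediate-early genes, nor TXNDC5 and ITGB7 with only the compared groups in the fit. Of 27 integrins and adhesion receptors 6 fell and 1 rose, the same adjusted over the list alone and 9 and 0 after scaling (camera adjusted p = 1.7e-08, adjusted p = 0.20 with an estimated correlation). The list median was 0.05 with shN2_1 and -0.20 with shN2_2. NCAM1, a neural adhesion molecule also found on myeloma cells, fell from 3.16 to 1.82 and 1.29 TPM, CDH2 from 23.8 to 18.2 and 16.4 TPM, and ITGB7 from 8968 to 6934 and 8049 TPM. Secreted matrisome factors were split, with 5 of 58 higher and 6 lower, or 5 and 8 adjusted over the list alone and 1 and 9 after median-ratio scaling (median 0.04, mean -0.02, lower by camera with adjusted p = 0.00070, adjusted p = 0.20 with an estimated correlation). Of 54 matrix regulators 7 rose and 3 fell, or 8 and 3 adjusted over the list alone and 3 and 5 after scaling, and the list was lower by camera although its median was 0.03 (adjusted p = 0.043, adjusted p = 0.44 with an estimated correlation). That call ended without shNTC replicate 2, shN2_1 replicate 1 or shN2_2 replicate 1 or 2 (adjusted p up to 0.17). The protease genes CTSF and CTSL rose, CTSF from 2.17 to 3.92 and 5.35 TPM, and TIMP1, an inhibitor of metalloproteases, fell from 28.7 to 21.3 and 17.6 TPM.

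With Notch2 in MM.1S, some genes of DNA replication and mitosis rose. Of 50 DNA replication and E2F targets 19 rose, or 27 adjusted over the list alone (median 0.24, camera adjusted p = 1.1e-09, adjusted p = 0.39 with an estimated correlation), and of 46 mitosis genes 14 rose, or 22 adjusted over the list alone (median 0.24, 6.6e-06, adjusted p = 0.44 with an estimated correlation). RFC4, a clamp loader subunit, rose from 112 to 144 and 154 TPM, CCNE2, a cyclin of the G1 to S transition, from 3.88 to 6.71 and 5.68 TPM, and NUSAP1, a spindle protein, from 104 to 135 and 136 TPM. After median-ratio scaling 5 and 1 members of these lists rose, and CCNE2 was not called with only the compared groups in the fit. HSPE1, a mitochondrial chaperonin, rose from 434 to 585 and 545 TPM. Oxidative phosphorylation (8 of 46 rose, 9 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.45 with an estimated correlation) and the proteasome (5 of 34 rose, 5 adjusted over the list alone, 0.0027, adjusted p = 0.39 with an estimated correlation) were higher lists. After scaling no oxidative phosphorylation gene rose and 1 fell, 1 proteasome gene rose, and neither list passed (adjusted p = 0.38 and 0.47). Without shNTC replicate 1 the oxidative phosphorylation list did not pass (adjusted p = 0.12), and without shNTC replicate 2 the proteasome list did not (adjusted p = 0.053). NF-kB targets (0 of 26, 0.0040, adjusted p = 0.13 with an estimated correlation), MHC class I (0 of 21, 0.039, adjusted p = 0.39 with an estimated correlation) and myeloma oncogenes (1 of 30 rose and 1 fell, 0.022, median 0.05 and mean -0.06, adjusted p = 0.44 with an estimated correlation) were lower lists. MHC class I did not pass without shNTC replicate 2 or 3, shN2_1 replicate 1 or shN2_2 replicate 2 (adjusted p up to 0.13), nor did myeloma oncogenes without shNTC replicate 1 or 2 or shN2_2 replicate 1 (adjusted p up to 0.080). Not past the threshold were p53 targets (6 of 27 higher in both), ribosome biogenesis (8 of 51 higher), ribosomal proteins (1 of 60 higher), interferon response (3 of 36 higher, GBP1 among them from 17.0 to 21.8 and 24.2 TPM), BCL2 family (3 of 15 higher), glycolysis and hypoxia (3 of 35 higher), matrix glycoproteins (3 of 25 higher and 1 lower), matrix-affiliated proteins (2 of 37 higher and 5 lower), unfolded protein response (2 of 33 higher), ATF4 (1 of 31 higher), Notch machinery (1 of 25 higher), collagens (0 of 5) and T and NK cell markers (0 of 6). After median-ratio scaling several of these turned, with 1 higher and 2 lower interferon genes, 1 and 2 matrix glycoproteins, 0 and 2 unfolded protein response and Notch machinery genes, and 0 and 1 BCL2 family and ATF4 genes. Of p53 targets and ribosome biogenesis genes 1 each was then higher. The unfolded protein response, ribosomal proteins, glycolysis and the Notch machinery then passed as lower lists (adjusted p = 0.0013, 0.0019, 0.029 and 0.048). Ribosome biogenesis, glycolysis and ribosomal proteins passed without shNTC replicate 1 (adjusted p = 0.0016, 0.0068 and 0.00054), and the first 2 also without shN2_2 replicate 2 (0.024 and 0.044) or 3 (0.030 and 0.018). The unfolded protein response and T and NK cell markers passed without shNTC replicate 2 (0.0496 and 0.033) or 3 (0.042 and 0.043), and matrix-affiliated proteins and glycolysis without shNTC replicate 3 (0.030 and 0.0087). In lists with under 5 tested genes, NOTCH2 and its ligand JAG1 were lower among Notch receptors, CD68 among myeloid markers, and PECAM1 and ESAM among stromal markers, and no epithelial or erythroid marker was called in both hairpins. The JAG1 fall, from 11.6 to 9.41 and 8.48 TPM, was not called without shNTC replicate 1 or 2 or any single library of shN2_1 (adjusted p up to 0.11), and PECAM1 not without shNTC replicate 1 or 2 or shN2_1 replicate 2 or 3 (adjusted p up to 0.099).

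Both Notch2 hairpins of MM.1S shared 1466 higher and 193 lower genes, with 62 in opposite directions, where independent calls would share 613 and 18.6. After median-ratio scaling they shared 271 and 520. Across genes, the changes with shN2_1 and shN2_2 correlated at 0.410, below the 0.502 that shared controls alone gave in simulations. Changes with 1 hairpin only also lower a correlation, and the covariance was 0.0315 against 0.0174 in the simulations. The changes with shN2_1 correlated more with those of shN1_2, a hairpin against the other receptor (0.656, 1111 higher and 123 lower genes shared, where independent calls would share 323 and 9.49). Their covariance was 0.0444, against 0.0171 in the simulations. All 4 hairpins of MM.1S shared 107 higher and 23 lower genes, or 37 and 57 after scaling. Genes of ribosomal RNA took 0.909% to 1% of the reads in the MM.1S shNTC libraries and 1.02% to 1.36% in the 6 Notch2 libraries. The total of 1659 was 1087 without shNTC replicate 2, and 1057 and 940 without shN2_1 replicate 1 and 3.

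Comparing the receptors within MM.1S, 1009 genes were higher and 3690 lower in the Notch1 than in the Notch2 groups, or 1936 and 1604 after median-ratio scaling. Apart from NOTCH1 (log2 -1.68, adjusted p = 7.6e-08), the chemokine gene CXCL10 (log2 -0.91, adjusted p = 0.00069), PHLDA3 (log2 -0.84, adjusted p = 0.00013) and CD38, a plasma cell surface enzyme (log2 -0.82, adjusted p = 0.00045), were lower in the Notch1 groups. CCL3 and CCL3L3, chemokine genes of the MIP-1 alpha family, were higher there (log2 1.33 and 1.45, adjusted p = 0.00021 and 0.00035). FOS and CCL4 were also higher (log2 1.96 and 1.55, adjusted p = 0.028 and 0.023), but both lost the call without shN1_1 replicate 2, shN1_2 replicate 1 or shN2_1 replicate 1 or 3, and FOS also without shN2_2 replicate 1 (adjusted p up to 0.072 for FOS and 0.061 for CCL4). Without the 3 libraries high for immediate-early genes, the count was 2062 in place of 4699.

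The RPMI-8226 Notch1 hairpins went with a broad fall of interferon-induced and antigen presentation genes. It was far stronger with shN1_2, which left more NOTCH1, than with shN1_1. CXCL10, a chemokine gene induced by interferons, fell from 419 ± 20.2 to 190 ± 4.21 TPM with shN1_1 (log2 -1.14, SE 0.17, adjusted p = 0.00081) and to 9.16 ± 1.20 with shN1_2 (log2 -5.45, adjusted p = 3.5e-11). MMP13, a collagenase, fell from 276 ± 5.11 to 152 ± 5.16 and 14.5 ± 1.04 TPM (log2 -0.86 and -4.20, SE 0.08). IFIT1, an antiviral protein gene, fell from 262 ± 9.35 to 178 and 21.3 TPM, while ISG15 and MX1 were at 2136 and 580 TPM with shN1_1 against 2608 and 687 in shNTC (adjusted p = 0.19 and 0.14) and fell to 320 and 130 TPM with shN1_2. CCL8, a chemokine, fell from 19.3 ± 0.333 to 2.84 ± 0.379 TPM with shN1_1 and was at 0.0262 TPM with shN1_2. CXCR3, the receptor of CXCL10, rose from 9.86 ± 0.816 to 22.8 ± 1.15 and 56.9 ± 4.26 TPM (log2 1.17 and 2.47, SE 0.07). The signalling factor gene LEFTY2 rose from 6.06 to 12.8 and 23.5 TPM, and PCP4, a calmodulin regulator, from 16 to 23.5 and 87.5 TPM. SPP1, which encodes the bone matrix protein osteopontin, fell alike with both hairpins, from 604 ± 58.5 to 167 and 185 TPM (log2 -1.85 and -1.70).

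Of 46 interferon response genes 26 fell and none rose in both Notch1 hairpins of RPMI-8226, or 28 adjusted over the list alone (median log2 -1.20, camera adjusted p = 2.0e-37, adjusted p = 0.043 with an estimated correlation). The list's median was -0.29 with shN1_1 and -2.07 with shN1_2. Of 21 MHC class I genes 13 fell, or 14 adjusted over the list alone (camera adjusted p = 2.2e-14, adjusted p = 0.0015 with an estimated correlation), among them HLA-F (45.2 to 35.9 and 10.5 TPM), the peptide transporter gene TAP1 (352 to 266 and 94.2 TPM) and the immunoproteasome gene PSMB9 (433 to 369 and 163 TPM). Of 29 NF-kB targets 14 fell, or 15 adjusted over the list alone (camera adjusted p = 0.00013, adjusted p = 0.026 with an estimated correlation), with the chemokine gene CCL3 at 16.3, 8.56 and 4.01 TPM and the ubiquitin ligase gene BIRC3 at 31.2, 24.3 and 9.88 TPM in shNTC, shN1_1 and shN1_2. Cytoplasmic ribosomal proteins rose, 34 of 60 in both hairpins and 47 adjusted over the list alone (median 0.20, camera adjusted p = 7.6e-30, adjusted p = 0.0039 with an estimated correlation). RPL5 rose from 986 ± 13.8 to 1152 and 1500 TPM, and RPL7 from 445 to 515 and 647 TPM. Of 34 cholesterol and fatty acid synthesis genes 6 rose, or 7 adjusted over the list alone (camera adjusted p = 1.7e-05, adjusted p = 0.31 with an estimated correlation), with the kinase gene PMVK at 109, 129 and 152 TPM and FASN at 262, 322 and 322 TPM. Oxidative phosphorylation was a higher list with 1 of 46 called, UQCRH (camera adjusted p = 0.00068, adjusted p = 0.49 with an estimated correlation). With shN1_2 alone 25 of the 46 were higher, and with shN1_1 1. These 6 lists passed, and 4 of them held with an estimated correlation.

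Among plasma cell genes in RPMI-8226 Notch1, 8 of 27 fell and 5 rose without a shift of the list. ELL2, an elongation factor needed for antibody secretion, fell from 35.8 to 23.2 and 9.92 TPM, POU2AF1, a coactivator of B lineage genes, from 184 to 146 and 80.7 TPM, and CD38 from 249 to 214 and 116 TPM. IL6ST, the signalling subunit of the interleukin-6 receptor, fell from 54.6 to 32.6 and 29.6 TPM (log2 -0.74 and -0.88), with 7 of 32 myeloma oncogenes lower and 4 higher. MCL1, a survival protein of the BCL2 family, fell from 559 to 479 and 306 TPM, but without shNTC replicate 3 or shN1_1 replicate 3 the shN1_1 call ended (adjusted p = 0.065 and 0.074). CCNE2 fell from 16.7 to 9.84 and 8.86 TPM among the 9 of 50 DNA replication and E2F targets that were lower. Further lists that did not pass held, as genes higher and lower in both hairpins, 5 and 18 of 74 secreted matrisome factors, 3 and 9 of 53 matrix regulators, 3 and 4 of 27 matrix glycoproteins, 2 and 4 of 38 matrix-affiliated proteins, 0 of 7 collagens and 3 and 7 of 28 integrins and adhesion receptors. They also held 0 and 3 of 21 B cell genes, 0 and 5 of 25 p53 targets, 1 and 3 of 33 unfolded protein response genes, 1 and 1 of 32 ATF4 genes, 0 and 2 of 45 mitosis genes, 0 of 51 ribosome biogenesis genes, 2 and 0 of 39 glycolysis genes, 0 and 2 of 15 BCL2 family genes and 0 of 34 proteasome genes. The Notch machinery held 0 and 3 of 27, Notch receptors and ligands 1 and 1 of 6, and markers of T and NK cells 1 and 0 of 8, myeloid cells 0 of 7, stromal cells 0 and 2 of 4, epithelial cells 3 and 2 of 11 and erythroid cells 0 of 3. After median-ratio scaling 3 mitosis genes rose and 2 fell, and 4 ribosome biogenesis genes rose in a list that then passed as higher (adjusted p = 0.037). E2F targets passed without shNTC replicate 3 or shN1_2 replicate 1 or 3 (adjusted p = 0.036, 0.025 and 0.037), epithelial markers without shNTC replicate 3 or shN1_2 replicate 1 (0.045 and 0.036), the Notch machinery without shNTC replicate 1 (0.048) and ribosome biogenesis without shN1_2 replicate 2 (0.035).

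In all, 546 genes were higher and 987 lower in both Notch1 hairpins of RPMI-8226, with 103 in opposite directions, where independent calls would share 135 and 353. After median-ratio scaling the counts were 734 and 823.

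**Figure D4:**
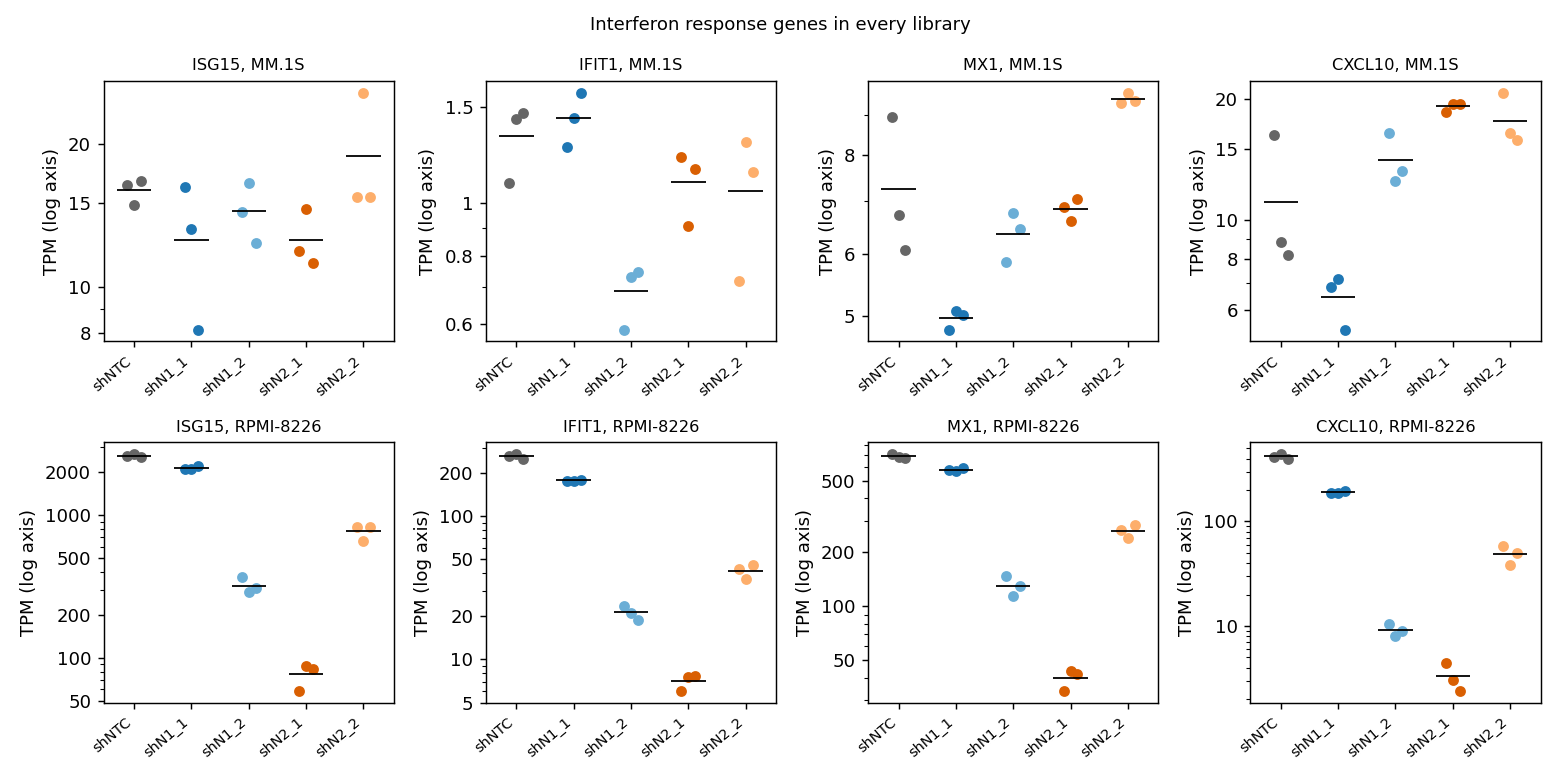
TPM of the interferon-induced genes ISG15, IFIT1, MX1 and CXCL10 in every group of both lines (log axis), with a dot per library and a line for the mean of 3. In RPMI-8226 CXCL10 went from 419 in shNTC to 190, 9.16, 3.28 and 48.7 TPM with shN1_1, shN1_2, shN2_1 and shN2_2.

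The RPMI-8226 Notch2 hairpins went with lower levels of every tested interferon response gene and with a higher list of ribosomal proteins. CXCL10 fell from 419 to 3.28 ± 1.02 TPM with shN2_1 and to 48.7 ± 9.92 with shN2_2 (log2 -6.83 and -3.11, SE 0.17, adjusted p = 2.2e-12 and 2.3e-08). ISG15, a ubiquitin-like protein gene, fell from 2608 ± 57.4 to 76.7 ± 15.9 and 773 ± 95 TPM (log2 -5.10 and -1.76, SE 0.13), and MX1, an antiviral GTPase gene, from 687 to 39.8 and 264 TPM (log2 -4.10 and -1.38, SE 0.10). MMP13 fell from 276 to 7.32 and 51.2 TPM. CCL8 was at 0.116 TPM with shN2_2 and listed at 0 in the 3 shN2_1 libraries, where the fitted fold is no bound on the change. CXCR3 rose from 9.86 to 56.3 and 43.3 TPM (log2 2.46 and 2.08, SE 0.07), and ALOX5AP, which activates leukotriene synthesis, from 6.68 to 21.0 and 32.0 TPM (log2 1.58 and 2.18, SE 0.10). DDIT4, a stress-induced inhibitor of mTORC1, rose from 252 ± 3.65 to 451 and 1227 ± 82.7 TPM (log2 0.84 and 2.28). ID3, an inhibitor of basic helix-loop-helix factors, rose from 21.7 to 50.5 and 111 TPM, and SPP1 fell with shN2_1 to 232 TPM and was at 686 ± 101 with shN2_2 (adjusted p = 0.15).

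All 46 interferon response genes fell in both Notch2 hairpins of RPMI-8226, and all 46 also fell adjusted over the list alone (median -2.17, camera adjusted p = 5.6e-38, adjusted p = 0.044 with an estimated correlation). The median was -3.15 with shN2_1 and -1.20 with shN2_2. Of 21 MHC class I genes 17 fell, also 17 adjusted over the list alone (camera adjusted p = 5.4e-12, adjusted p = 0.0033 with an estimated correlation), with TAP1 at 69.8 and 166 TPM and HLA-F at 7.22 and 23.9 TPM. Of 29 NF-kB targets 12 fell and 2 rose, also 12 and 2 adjusted over the list alone (camera adjusted p = 0.00098, adjusted p = 0.044 with an estimated correlation). BIRC3 fell to 10.9 and 16.5 TPM, and LTB, the lymphotoxin beta gene, rose from 62.7 to 131 and 138 TPM. Of 60 ribosomal protein genes 45 rose, or 51 adjusted over the list alone (median 0.27, camera adjusted p = 2.0e-27, adjusted p = 0.0054 with an estimated correlation), with RPL5 at 1641 and 1230 TPM. Of 34 cholesterol and fatty acid synthesis genes 15 rose and none fell, with the same count adjusted over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.23 with an estimated correlation). DHCR7, of the last step of cholesterol synthesis, rose from 220 to 298 and 293 TPM and PMVK from 109 to 164 and 157 TPM. Of 32 ATF4 genes 6 rose and 2 fell, also 6 and 2 adjusted over the list alone and 12 and 1 after median-ratio scaling (camera adjusted p = 0.00013, adjusted p = 0.66 with an estimated correlation), with PYCR1, of proline synthesis, at 106, 154 and 158 TPM, and NUPR1 lower. That list rested on shN2_2, with 26 higher and 2 lower (median 0.35), against 6 and 7 with shN2_1 (median 0.02). Of 46 oxidative phosphorylation genes 13 rose and 3 fell, 14 and 4 adjusted over the list alone and 22 and 3 after scaling (camera adjusted p = 0.016, adjusted p = 0.66 with an estimated correlation), with 24 higher and 3 lower in shN2_2 but 13 and 15 in shN2_1. Lower lists were DNA replication and E2F targets (2 of 50 rose and 10 fell, 2 and 7 adjusted over the list alone, 0.021, adjusted p = 0.86 with an estimated correlation) and the Notch machinery (1 of 27 rose and 10 fell, also 1 and 10 adjusted over the list alone, 0.032, adjusted p = 0.32 with an estimated correlation). KAT2B, an acetyltransferase that acts with the Notch complex, fell from 26.1 to 12.7 and 15.7 TPM and ADAM17, a protease of surface proteins, from 15.9 to 10.8 and 10.3 TPM. Epithelial markers were a higher list (4 of 11 rose, also 4 adjusted over the list alone, 0.033, adjusted p = 0.32 with an estimated correlation), with the keratin gene KRT7 at 7.49, 13.6 and 16.4 TPM and EPCAM at 80.2, 94.2 and 101 TPM, a call that ended for the list without shNTC replicate 1 (adjusted p = 0.071) and after scaling (adjusted p = 0.061).

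Plasma cell genes in RPMI-8226 Notch2 were split, with 8 of 27 higher and 9 lower. PRDM1, the master regulator of plasma cells, fell from 37.7 to 17.5 and 23.5 TPM and ELL2 from 35.8 to 14.2 and 16.5 TPM. Among 21 B cell genes 4 rose and 2 fell, FCRLA from 7.38 to 20.5 and 21.9 TPM. Among myeloid markers 4 of 7 rose, S100A9, a calcium-binding protein of granulocytes, from 26.4 to 56.1 and 54.2 TPM. Among 28 integrins and adhesion receptors 7 rose and 8 fell, with the leukocyte integrin gene ITGB2 at 4.07, 9.35 and 10.4 TPM. MCL1 fell from 559 to 170 and 390 TPM among 15 BCL2 family genes, of which 1 rose and 3 fell. None of these lists passed, and the others that did not held, as genes higher and lower, 14 and 22 of 74 secreted matrisome factors, 9 and 19 of 53 matrix regulators, 6 and 5 of 27 matrix glycoproteins, 2 and 4 of 38 matrix-affiliated proteins and 0 and 1 of 7 collagens. They also held 2 and 7 of 25 p53 targets, 4 and 6 of 32 myeloma oncogenes, 4 and 5 of 33 unfolded protein response genes, 6 and 3 of 45 mitosis genes, 5 and 9 of 51 ribosome biogenesis genes, 5 and 13 of 39 glycolysis genes and 1 and 4 of 34 proteasome genes. Notch receptors and ligands held 1 and 1 of 6, T and NK cell markers 2 and 0 of 8, stromal markers 0 and 1 of 4 and erythroid markers 0 of 3. After median-ratio scaling the balance turned for the unfolded protein response (8 and 4) and the proteasome (4 and 3), and mitosis genes numbered 13 and 3. Glycolysis passed without shNTC replicate 1 or shN2_2 replicate 2 (adjusted p = 0.046 and 0.027), B cell genes without shNTC replicate 2 (0.047) and T and NK cell markers without shNTC replicate 3 (0.039).

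Both Notch2 hairpins of RPMI-8226 shared 1673 higher and 2681 lower genes, with 185 in opposite directions, where independent calls would share 433 and 1050. After median-ratio scaling they shared 2215 and 2352. All 4 hairpins shared 410 higher and 735 lower genes, or 547 and 629 after scaling. Across genes, which are not independent replicates, the changes with shN1_2 correlated more with those of shN2_1 (0.836) than with those of shN1_1 (0.536), where shared controls alone gave about 0.50 in simulations. The covariances were 0.166 and 0.0575, against 0.0139 in the simulations of either pair.

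Comparing the receptors within RPMI-8226, 2143 genes were higher and 1468 lower in the Notch1 than in the Notch2 groups. Apart from NOTCH2 itself (log2 1.89), the interferon-induced genes IFIT1, ISG15 and MX2 were higher on average in the Notch1 groups (log2 1.80, 1.77 and 1.75, IFIT1 adjusted p = 2.4e-09). SPP1, ALOX5AP and S100A9 were lower there (log2 -1.17, -1.09 and -1.07, SPP1 adjusted p = 5.6e-08), as was NOTCH1 (log2 -1.52). The order of the interferon-induced genes was not shared by both Notch1 hairpins, since shN1_2 lay below shN2_2. IFIT1 was at 178 TPM with shN1_1, 21.3 with shN1_2, 7.09 with shN2_1 and 41.8 with shN2_2. ISG15 was at 2136, 320, 76.7 and 773 TPM in that order. The adjusted p measures the spread between libraries, not between hairpins.

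The last comparison asked which changes differed between the lines, over 14709 genes. For Notch1, 2145 genes changed more upward in MM.1S and 796 more upward in RPMI-8226, or 1430 and 1693 after median-ratio scaling. For Notch2 the counts were 5306 and 1248, or 2348 and 2584 after scaling. CXCL10 differed most in both, with a mean change of -0.15 in MM.1S and -3.29 in RPMI-8226 for Notch1 (adjusted p = 1.5e-09), and of 0.76 and -4.97 for Notch2. GBP1, an interferon-induced GTPase gene, changed by -0.03 and -2.32 for Notch1 and by 0.42 and -3.04 for Notch2. CXCR3 changed by 0.02 in MM.1S and 1.82 in RPMI-8226 for Notch1, and by 0.20 and 2.27 for Notch2. As lists, interferon response and MHC class I genes were more upward in MM.1S with both receptors, and cholesterol synthesis genes more upward in RPMI-8226, and all 3 held with an estimated correlation.

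Some genes changed alike in both lines. For Notch1, 69 genes rose in both hairpins of both lines where 9.95 were expected for independent genes (Fisher's exact test, p = 8.6e-39, adjusted p = 1.4e-37 over 16 tests), and 15 fell where 5.22 were expected (adjusted p = 0.00043). Genes are not independent, so the p of these tests can be too small. The Notch1 changes followed exon length in both lines (Spearman -0.26 in MM.1S and -0.19 in RPMI-8226). Across 14709 genes the mean changes of the lines correlated at 0.119 for Notch1 and 0.0675 for Notch2. For Notch2, 180 rose where 140 were expected (adjusted p = 0.00043) and 26 fell where 29.0 were expected (adjusted p = 0.93), and 40 fell in MM.1S and rose in RPMI-8226 where 17.7 were expected (adjusted p = 2.8e-06). After median-ratio scaling 30 genes rose and 30 fell in both lines for Notch1 (9.31 and 11.1 expected, adjusted p = 1.1e-07 and 2.8e-06). For Notch2 47 then rose and 94 fell in both (33.4 and 69.2 expected, adjusted p = 0.016 and 0.0020), and 99 fell in MM.1S and rose in RPMI-8226 (65.8 expected, adjusted p = 4.6e-05). TCN2, the carrier of vitamin B12 into cells, fell in all 8 comparisons, from 64.4 to 43.1 through 48.2 TPM in MM.1S and from 129 to 53.1 through 93.9 TPM in RPMI-8226. Genes that rose in all 8 numbered 8 and genes that fell 2. For Notch1, DDIT4 rose and PECAM1 fell in both hairpins of both lines, although the DDIT4 call in MM.1S ended after median-ratio scaling and without any single library of the compared groups except shNTC replicate 2 (adjusted p up to 0.14). The PECAM1 call in RPMI-8226 ended without any single shNTC library or shN1_1 replicate 1 or 3 (adjusted p up to 0.088). For Notch2, the protease gene CTSF rose and S100A6 and CAPG, an actin-capping protein gene, fell in both hairpins of both lines.

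**Figure D5:**
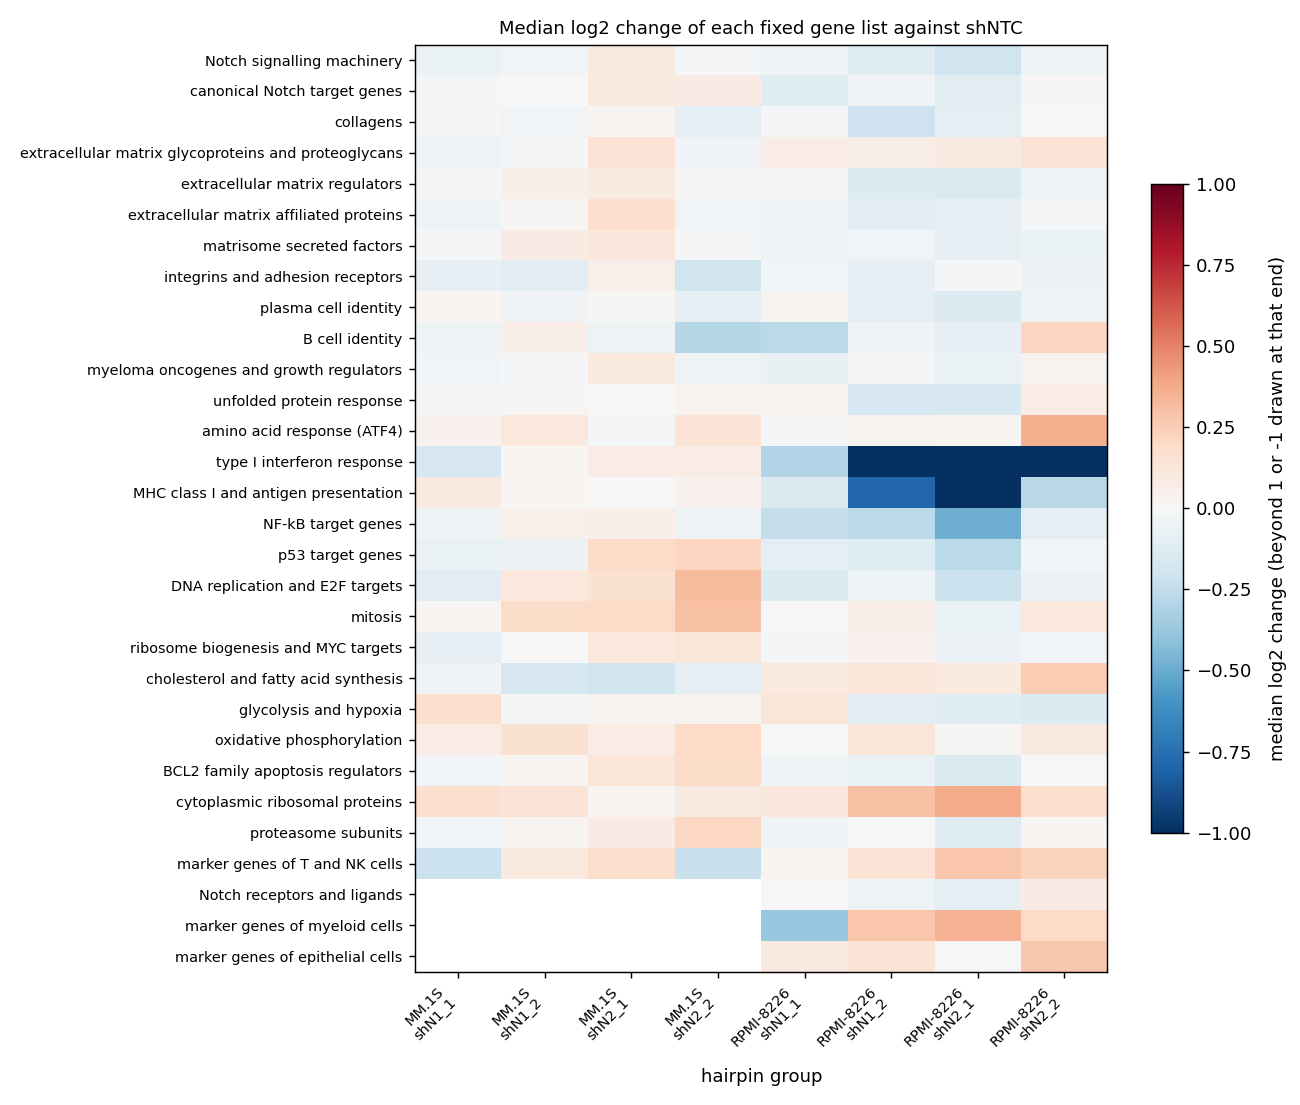
Median log2 change of the tested members of 30 gene lists (rows) in the 8 hairpin groups (columns), as colour, with values beyond -1 or 1 drawn at the end of the scale and blanks where fewer than 5 members were tested. The interferon response list ranged from -0.29 to -3.15 in the RPMI-8226 groups.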

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

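In this part, the tests of the immunoglobulin lambda share and of the shallowest library were planned. Those of receptor loss, control libraries, scaling, culture, gene length and other splits were chosen only after the result was seen.

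A test of the difference between the cell lines flagged every result given here as MM.1S minus RPMI-8226. For Notch1 it called 2941 genes, and for Notch2 6554. Of 100 splits of the libraries, the real one included, 3 gave as many genes for Notch1 (real 2941, highest other 3560) and 1 for Notch2 (real 6554, highest other 3021). Both shares are under 0.05, so a random labelling of these libraries seldom gave such counts. Splits mix groups that differ for any reason, so they cannot exclude differences between cultures.

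As lists with Notch1, the same test flagged interferon response (median difference 1.03), MHC class I (0.51) and NF-kB targets (0.27) as more upward in MM.1S. It flagged ribosome biogenesis (-0.0624), cholesterol and fatty acid synthesis (-0.15) and ribosomal proteins (-0.0494) as more upward in RPMI-8226. With an estimated correlation interferon response, MHC class I, NF-kB targets and cholesterol synthesis held (adjusted p = 0.0061, 3.4e-05, 0.043 and 0.023), and ribosome biogenesis and ribosomal proteins did not (adjusted p = 0.96 for both). The interferon list fell in RPMI-8226 (median -1.20) and changed little in MM.1S (-0.07).

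As lists with Notch2, interferon response (2.13), MHC class I (0.61), DNA replication and E2F targets (0.36) and the proteasome (0.16) were more upward in MM.1S. Cholesterol synthesis (-0.31), B cell identity (-0.25), ribosomal proteins (-0.21), matrix glycoproteins (-0.20) and ATF4 genes (-0.15) were more upward in RPMI-8226. Secreted matrisome factors (0.0709) and integrins and adhesion receptors (0.0735) were also flagged, where the list test placed them as more upward in RPMI-8226 although the median differences lay above 0. With an estimated correlation interferon response, MHC class I, B cell identity, cholesterol synthesis and ribosomal proteins held (adjusted p = 0.0036, 0.00077, 0.023, 0.0032 and 0.034), and the other 6 lists did not (adjusted p = 0.39 to 0.60). Here too the interferon list fell in RPMI-8226 (median -2.17) and changed little in MM.1S (0.06), where these genes started low.

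Among single genes with Notch1, the test of the difference flagged CXCL10 (3.14), CCL3L3 (2.32), GBP1 (2.29) and TNFSF10 (2.28) as more upward in MM.1S and AHNAK (-2.53), CXCR3 (-1.80) and LEFTY2 (-1.78) as more upward in RPMI-8226. The small RNA gene MIR6732 (2.71) lost its call with a pseudocount of 0.1, without a filter, after median-ratio scaling, and without any single library of the compared groups except RPMI-8226 shN1_1 replicate 1, RPMI-8226 shN1_2 replicate 3, MM.1S shN1_1 replicate 2 and MM.1S shN1_2 replicate 2 (adjusted p = 0.057 to 0.12). MIR6779 (-1.47) lost it without a filter and without shNTC replicate 1 or 2 of either line, RPMI-8226 shN1_1 replicate 3, MM.1S shN1_1 replicate 1 or MM.1S shN1_2 replicate 1 (adjusted p = 0.050 to 0.088). MIR637 (-1.95) was at -1.22 without RPMI-8226 shNTC replicate 3 and lost its call there (adjusted p = 0.088).

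With Notch2 the test flagged CXCL10 (5.73), IFIT1 (3.66), HERC5 (3.65), PLAAT2 (3.61) and GBP1 (3.46) as more upward in MM.1S. It flagged ALOX5AP (-2.42), AHNAK (-2.22), CXCR3 (-2.07), LEFTY2 (-1.97) and FCRLA (-1.86) as more upward in RPMI-8226. Without MM.1S shNTC replicate 1 the difference of AHNAK was -1.42.

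The first pattern weighed was the fall of interferon response genes in RPMI-8226, by a list median of -2.07 with shN1_2, -3.15 with shN2_1 and -1.20 with shN2_2 but -0.29 with shN1_1. The tables argue against scaling between libraries, since the Notch2 median was -2.13 after median-ratio scaling, and against a response present in the control libraries alone, since the shN1_1 libraries lay 1.89 above those of the other 3 hairpins. They also argue against a fall graded by the loss of NOTCH1 mRNA, since shN1_1 left less NOTCH1 than shN1_2 and yet its list median per library was 1.83 higher. For Notch2 the order was the one such a grading needs, with shN2_1 below shN2_2 by a difference of -1.94, from 2 hairpins only. Culture or transduction differences between the groups stay open, since the change from shN1_1 to shN1_2 correlated with that from shNTC to Notch2 at 0.649 across genes (0.616 without the interferon list), which effects of the hairpins on other genes could also give.

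The next pattern weighed was the excess of higher genes in MM.1S Notch2, 88.4% of those called in both hairpins (1466 higher and 193 lower). It was not there after median-ratio scaling (271 higher and 520 lower) or in the authors' tables (229 and 626). The tables argue against the shallowest library, since without shN2_2 replicate 2 the share was 86.2%. Without the immunoglobulin lambda genes in the TPM total the share was 75.9% (732 higher and 232 lower), which lay between the bounds set for that test. The larger share of these genes in the control libraries may therefore account for part of the excess in TPM, and how much stays open. No biological explanation was tested, nor was the higher share of ribosomal RNA reads in the Notch2 libraries given above.

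The last pattern weighed was the rise of ribosomal protein genes, which have short exons (median 1165 bases against 3094 for the genes tested in MM.1S). After removal of each library's trend with exon length, the list medians were 0.0667 in MM.1S Notch1 (from 0.15), 0.19 in RPMI-8226 Notch1 (from 0.20) and 0.25 in RPMI-8226 Notch2 (from 0.27), so 7, 24 and 38 genes rose in both hairpins in place of 22, 34 and 45. In RPMI-8226 this argues against the trend as the whole cause, since both medians lay above 0 by more than the SD among the genes (0.0985 and 0.138, from 0.0838 and 0.121) and the list passed camera (adjusted p = 1.0e-19 and 1.0e-18). Its calls with an estimated correlation ended (adjusted p = 0.17 and 0.22, from 0.0039 and 0.0054), as the estimated correlation rose from 0.103 to 0.313 with folds about as large. In MM.1S Notch1 the list also passed camera (adjusted p = 4.1e-05), but the median lay within the SD (0.104), so a trend with gene length could account for part or all of the rise and stays open there.

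Other splits of the libraries were counted for each number of genes. For each hairpin against shNTC there are only 10 splits, too few for a share under 0.05, and only the real 1 gave as many genes. The real counts and the highest other were 833 and 1, 2047 and 1, 3601 and 1, and 3912 and 7 in MM.1S, and 2039 and 4, 7586 and 1, 8157 and 0, and 5964 and 2 in RPMI-8226. Of 100 splits, only the real 1 reached the genes called in both hairpins for MM.1S Notch1 (405, highest other 202), MM.1S Notch2 (1659, highest other 1089) and RPMI-8226 Notch2 (4354, highest other 3929). For RPMI-8226 Notch1, 2 of 100 reached 1533, but the other split called 4984, which points to a structure of the samples. Between the receptors 1 of 100 reached the real count in each line (4699, highest other 2481, and 3611, highest other 2811). These shares under 0.05 set the real grouping apart from random labels, but cannot tell effects of the hairpins from differences between cultures. Chance cannot be excluded for the number of lists past the threshold. There 15, 23, 69 and 32 of 100 splits reached the 11, 13, 6 and 10 lists of MM.1S Notch1 and Notch2 and RPMI-8226 Notch1 and Notch2. Other splits gave medians of 7, 7, 6 and 8 and at most 16, 21, 14 and 15.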

How the results depend on the processing

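Voom and the fit without the 3 libraries high for immediate-early genes were chosen only after the results were seen. In RPMI-8226 the total gene counts of every hairpin, receptor and receptor comparison kept within 1.5 times of their values under every alternative, and a pseudocount of 0.1 and a minimum TPM of 5 did so in MM.1S too. Counts by direction moved more in RPMI-8226. Higher genes with shN2_1 went from 2552 to 3890 (variance-stabilised), 3858 (median-ratio) and 4085 (voom), and lower ones from 5605 to 3679 (authors' adjusted p). Higher genes with shN1_1 went from 765 to 1159 (variance-stabilised), 504 (without shNTC replicate 2) and 501 (without shN1_1 replicate 2), and lower ones from 1274 to 846 (without shNTC replicate 1). Those higher in both Notch1 hairpins went from 546 to 844 (variance-stabilised). The MM.1S Notch1 counts were the least stable. A depth of 6532988 reads in MM.1S shN2_2 replicate 2 limits what that group shows at low TPM. The causes of the changes given here were not tested, except that leaving out libraries lowers their number.

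Genes called in both MM.1S Notch2 hairpins numbered 882 with the variance-stabilised values. Without a filter MM.1S shN1_1 had 380 genes, shN1_2 1307 and both 190. After median-ratio scaling shN2_1 had 2174 and both Notch2 hairpins 791. With only the compared groups in the fit, shN1_1 had 43, shN1_2 468, shN2_2 784, both Notch1 hairpins 26 and both Notch2 hairpins 416. With voom shN1_1 had 1446, both Notch1 hairpins 666 and both Notch2 hairpins 941. Without the 3 libraries high for immediate-early genes the counts were 138, 1111 and 1969 for shN1_1, shN1_2 and shN2_1, 94 and 913 for both hairpins of Notch1 and Notch2, and 2062 between the receptors. By the authors' deposited adjusted p they were 1377 for shN1_1, 2427 for shN2_2, 643 for both Notch1 and 855 for both Notch2 hairpins.

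With replicate number as a block, MM.1S shN1_1 had 518 genes, shN1_2 1694, shN2_1 3230, shN2_2 3484, both Notch1 hairpins 274, both Notch2 hairpins 1460 and the receptors 4217. RPMI-8226 had 1976, 7557, 8159, 5906, 1480, 4319 and 3513 in the same order, and the lines differed at 2822 and 6390 genes. Of the results for named genes over both lines, 32 lost their call with the block and 533 stayed as they were. Of the list results 1 lost its call and 113 stayed. Same-numbered libraries correlated in their deviations at -0.107 to 0.169 in MM.1S (median -0.0125) and at -0.0543 to 0.0857 in RPMI-8226 (median 0.00818). Differently numbered ones did so at -0.133 to 0.151 and -0.0867 to 0.0631, and not every library correlated best with one of its own number.

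With an estimated correlation 0 lists passed in MM.1S Notch1, 3 in MM.1S Notch2 and 4 in RPMI-8226 Notch2. With fry 4 lists passed in MM.1S Notch1, 21 in RPMI-8226 Notch1 and 26 in RPMI-8226 Notch2. Directions reversed with fry for 4 lists in MM.1S Notch2: matrix regulators (adjusted p = 0.18), myeloma oncogenes (0.887), ATF4 (0.0335) and MHC class I (0.782). They also reversed for matrix glycoproteins in RPMI-8226 Notch1 (0.00594) and Notch2 (0.00695). DNAJB11 in MM.1S Notch2 changed from 0.10 to -0.0284 with the variance-stabilised values, -0.0209 after median-ratio scaling, -0.0166 with voom and -0.0229 in the authors' tables.

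With 1 library left out, counts in MM.1S ran from 250 (without shN1_1 replicate 2) to 1040 (without shNTC replicate 3) for shN1_1, from 694 (without shN1_2 replicate 3) to 2140 for shN1_2, and from 1992 (without shN2_1 replicate 3) to 3602 for shN2_1. They ran from 2738 to 3943 for shN2_2, from 171 (without shN1_1 replicate 2) to 579 for both Notch1 hairpins, from 940 (without shN2_1 replicate 3) to 1749 for both Notch2 hairpins and from 3444 to 4832 between the receptors. Lists numbered 7 (without shNTC replicate 1) to 12 for Notch1 and 11 to 16 for Notch2. RPMI-8226 counts ran from 1379 to 1647, 6680 to 7115, 7162 to 7496, 4972 to 5381, 1075 to 1619 and 3698 to 4155, and lists from 6 to 8 and from 10 to 11. Between the receptors there they ran from 3022 to 3720, and between the lines from 2150 to 3032 and from 5678 to 6850.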

Other observations

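No test was added in this part after the results were seen, and the genes come from the same fits as those of the report. The Notch2 values of DEPTOR and TGFA were chosen after the values were seen.

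Several secreted factors and regulators of growth changed with all 4 hairpins in RPMI-8226. IGFBP4, which binds insulin-like growth factors, fell from 6.28 ± 0.344 to 2.01 and 0.699 TPM with shN1_1 and shN1_2 (log2 -1.44 and -2.50, SE 0.13, adjusted p = 1.3e-05 and 4.0e-09), and to 0.701 and 0.944 TPM with shN2_1 and shN2_2 (log2 -2.50 and -2.23). IGFBP2, of the same family, rose from 7.28 to 12.2 and 12.4 TPM with the Notch1 hairpins (log2 0.71 and 0.73, SE 0.09). CXCL12, the chemokine that holds plasma cells in the bone marrow, fell from 32.3 ± 1.33 to 24 and 14.8 TPM with the Notch1 hairpins and to 12.9 and 21.7 TPM with the Notch2 hairpins (log2 -1.30 and -0.57, SE 0.04). DEPTOR, an inhibitor of mTOR often high in myeloma, rose alike with all 4, from 60.8 to 91.2, 88.9, 95.3 and 88 TPM (log2 0.58, 0.54, 0.64 and 0.53, SE 0.04). The galectin gene LGALS9 fell from 85 to 71, 28.5, 18.7 and 43.6 TPM. TP53INP1, a p53-induced protein, fell from 32.2 to 19.7 and 16.4 TPM with the Notch1 hairpins (log2 -0.69 and -0.95, SE 0.10). MUC1, a mucin, and ELF3, an epithelial transcription factor gene, fell there too, MUC1 from 102 to 66.3 and 66.7 TPM and ELF3 from 39.4 to 18.6 and 9.81 TPM. With shN2_2 ELF3 was at 41.5 TPM (adjusted p = 0.65). The heat shock gene HSPA6 went in opposite directions between the Notch2 hairpins, from 2.25 to 0.715 TPM with shN2_1 and 19.3 with shN2_2 (log2 -1.17 and 2.84, SE 0.20).

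Single MM.1S genes rose with the Notch2 hairpins in lists that also held falls. CLEC7A, a receptor for fungal glucans, rose from 31.3 ± 4.27 to 47.1 and 50.1 TPM (log2 0.59 and 0.67, SE 0.09, adjusted p = 0.0015 and 0.00040). TGFA, a growth factor made as a membrane protein, rose from 10.8 to 16.1 and 16.3 TPM (log2 0.56 and 0.58, SE 0.09). MFGE8, which bridges dying cells to phagocytes, rose from 14 to 17.9 and 17.8 TPM (log2 0.34 and 0.33, SE 0.04).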
